A study of Arabidopsis thaliana with 6 samples.

How the data were processed

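Roots of 5-day-old Arabidopsis thaliana seedlings of the Col-0 ecotype were protoplasted, and fluorescent cells were collected by sorting. The series holds 6 samples, 3 from plants carrying WOX5::GFP and 3 from plants carrying pTMO5::GFP. WOX5 is a homeobox gene known as a marker of the quiescent centre, the slowly dividing core of the root stem cell niche. TMO5 encodes a basic helix-loop-helix factor known from young vascular and xylem cells. Samples were grouped by the reporter in their titles. The descriptions call the WOX5 samples quiescent centre and the TMO5 samples xylem, whereas the cell type tag has these words the other way round, so the groups are named by reporter throughout. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

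RNA was labelled with biotin and hybridised to Affymetrix arrays. Per the labels' protocols, some arrays of the larger project were labelled in 2 cycles and the rest in 1, and which protocol each of these 6 arrays received is not given in the sources used here. The authors deposited 1 table of intensity values on a linear scale, with 22810 probe sets on each array and no detection calls. The software that made these values, and its settings, are not given in the sources used here. Each array had a mean intensity of 250.0 after trimming 2% of values at each end, so the arrays had been brought to a common scale before deposit. Scaling of this kind fixes the total signal of an array and not its median. Median intensities were 92.2, 92.6 and 91.7 on the WOX5 arrays and 74.5, 70.3 and 68.1 on the TMO5 arrays.

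From these values, log2 intensities were computed after raising values under 1 to 1, which affected 1036 values. The 64 control probe sets were set aside and 22746 were tested, with no filter on dim probe sets and no further normalization. Groups were compared as WOX5 minus TMO5 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, statmod 1.5.0 installed), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A difference that passed is described as higher or lower, or as a rise or fall. Arrays have no read depth, and the number of arrays limits the precision. Background was set for each group as the 95th percentile of 27 bacterial control probe sets without a spike, which was 30.8 in WOX5 and 23.4 in TMO5 intensity units. Where the dimmer group lay within background, a fold change is given as a lower bound against that level.

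Gene names came from the platform annotation supplied with the series, updated through the TAIR10.1 gene table. It named 1 gene for 13513 of the tested probe sets, several for 503 and none for 8730. No gene was named from a probe set with several genes. For a gene with several probe sets, the one with the highest mean over all arrays was used, which left 13355 genes, of which 11798 are known here by locus alone. The genome build behind the probe design is not given in the sources used here, so no coordinates are printed.

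Before the data were examined, 18 gene lists with 312 genes were written, together with the main test, the alternatives and the rule for naming genes. Only 41 of the listed genes had a named probe set, and 5 lists had the 3 or more members required for a test. Because of this, 6 larger lists by locus were added after the annotation, control values and array correlations had been seen and before any fold change was computed. They cover mitosis, DNA replication, core histones, cytosolic ribosomal proteins, class III peroxidases and root hairs, with 204 of 353 genes measured. The minimum list size, the background level, the rule for matching listed symbols to loci and the 31 families of genes sharing a symbol stem were set after a first look at fold changes. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Camera p-values were adjusted within the fixed lists, within the added lists and within the symbol families. List medians were also set against 10000 random lists of matched brightness. Spiked controls and the 3′ to 5′ ratios of control transcripts were compared by exact two-sided permutation tests, whose smallest possible p is 0.1 with 3 arrays per group.

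Genes named in the text are the 10 largest rises and the 10 largest falls among called probe sets with 1 gene whose groups did not overlap, 18 core genes whatever their result, and for each list the 2 largest rises and falls among members that passed. Where no member of a list passed, the one with the smallest p is named. Of the core genes, 15 had no named probe set, WOX5 and TMO5 among them, so the planned check of the reporters' own transcripts could not be run. The planned test of transcription factors was not run because the gene tables hold no descriptions. Other list members named here were chosen after their values were seen.

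Alternatives were quantile normalization, centring each array on its median, a filter on dim probe sets, a floor at the 20th percentile of all values, an intensity trend with robust variances, array weights, a replicate block, a 2-fold minimum and leaving out each array in turn. The tests were tried on simulated data with the arrays' own means and spread. Of 200 changed probe sets, 3% of the 2-fold and 81% of the 4-fold changes were recovered, and 2 unchanged probe sets were called. The real data gave 5411 calls, many more than 200, so these recovery shares do not carry over to the main test. Drawing used Python 3.11.15 and matplotlib 3.10.9.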

Results

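The data are expression levels from 6 arrays of sorted root cells, 3 from WOX5::GFP and 3 from pTMO5::GFP seedlings aged 5 days. The series concerns the gene networks that keep root stem cells in place and give them identity, and its design compares the cells marked by these reporters. Arrays of one group resembled each other more than arrays of the other group. Principal components were computed without the dimmest 1/3 of probe sets. The first held 81.3% of the variance and separated the groups, and the second held 8.16%. On the second component WOX5 replicate 2 lay at -42.4 and the other WOX5 arrays at 24.7 and 24.3. In the brighter part of the probe sets, log2 values of WOX5 replicate 2 differed from WOX5 replicate 1 with an SD of 0.53, against 0.25 between WOX5 replicates 1 and 3. Among calls made without WOX5 replicate 2, 61.1% of the 2854 rises were brighter on it than the mean of replicates 1 and 3, and 61.4% of the 2000 falls were dimmer. Of all tested probe sets, 52.5% were brighter on it. Each reporter was used on 1 set of arrays, so handling of the arrays and cell type cannot be told apart.

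The first comparison asked which transcripts differ between WOX5-marked and TMO5-marked cells. The largest rises in WOX5 cells by measured log2 difference were of genes within background in TMO5 cells, which such a ranking favours. AT3G60650 had an intensity of 956 ± 691 (SD, n = 3) in WOX5 and 1.87 ± 1.35 in TMO5 cells, at least 34.8-fold higher (limma adjusted p = 0.0014). AT3G23570 was at least 45.4-fold higher, AT4G26870 at least 60.4-fold and AT3G53040 at least 72.1-fold. The lower bounds for AT5G51470, AT3G19520, AT5G02070, AT4G00750, AT1G26680 and AT5G53990 ran from 7.81-fold to 46.2-fold. The lowest, for AT5G53990, was 4.59-fold without WOX5 replicate 2. By comparison AT2G43480, above background in both groups, was 38.7-fold higher and fell outside this ranking.

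The largest falls included AT5G02640, at 40.1 ± 21.9 in WOX5 against 1919 ± 65.5 in TMO5 cells (SD, n = 3), a 55.6-fold difference (limma adjusted p = 0.0023), or 36.4-fold without WOX5 replicate 2. SAH7 was 29.5-fold lower in WOX5 cells, at 81.8 ± 27.9 against 2340 ± 352. MGL, which encodes methionine gamma-lyase, was at least 13.7-fold lower, and FOLB1, an enzyme of folate synthesis, at least 9.03-fold lower. GH3.3, an enzyme that joins auxin to amino acids, was at least 6.48-fold lower. The lower bounds for AT3G28420, AT5G24240, AT1G14890, AT2G28410 and AT2G20720 ran from 1.69-fold to 16.5-fold. The ranking used measured log2 differences, including WOX5 values within background. Some of these bounds therefore lie below folds measured above background, such as the 12.7-fold fall of AT1G71695.

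In all, 5411 of 22746 probe sets (23.8%) passed the threshold, 3252 higher and 2159 lower in WOX5 cells. Changes of at least 2-fold accounted for 2623 of the rises and 1103 of the falls. The groups did not overlap for 10632 probe sets (46.7%), where chance gives 10%. Among the calls, 2329 probe sets had no gene name, and the largest rise among them ran to 9582 ± 1265 in WOX5 against 36.4 ± 39.6 in TMO5 cells. The share of calls that were higher in WOX5 was 60.1%, but 47.2% with quantile normalization and 29.7% with arrays centred on their medians. The median log2 difference of all probe sets was 0.03, -0.14 and -0.35 under these 3 scalings, so a small shift shared by many genes has no settled direction. Leaving out 1 array gave 3288 calls without WOX5 replicate 1, 3507 without WOX5 replicate 3, and 3096, 2827 and 3018 without TMO5 replicates 1, 2 and 3.

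The second comparison asked whether genes known from the quiescent centre and stem cell niche were higher in one cell population. Of 7 measured members, 6 were higher in WOX5 cells and 0 were lower, and the count adjusted over the list alone was also 6. AGL42, a MADS-box gene, stood at 271 ± 38.4 in WOX5 against 21.2 ± 13.2 in TMO5 cells (SD, n = 3), at least 11.5-fold higher (limma adjusted p = 0.0060). JKD, a zinc finger regulator of ground tissue, was at least 10.4-fold higher and BRL1, a brassinosteroid receptor, at least 6.32-fold higher. ACR4, a receptor kinase of root tip stem cells listed in the gene table as CR4, was 5.75-fold higher, at 237 ± 80.3 against 40.2 ± 7.34.

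BBM, an AP2-domain factor of the stem cell niche, was 2.11-fold higher in WOX5 cells (limma adjusted p = 0.048), and the basic helix-loop-helix gene SPT was 1.98-fold higher (limma adjusted p = 0.047). The peptide gene CLE40 did not pass, with a log2 difference of -0.22 ± 0.18 (SE). It lay within background in WOX5 cells, at 27.2 against 31.4 in TMO5 cells, so this difference is poorly measured. The list's median log2 difference was 2.52, at percentile 99.96 of random lists of matched brightness. Camera gave an adjusted p of 0.0019 for the list over the 5 fixed lists, and an adjusted p of 0.35 with an estimated correlation. BBM lost its call with a floor at the 20th percentile (adjusted p = 0.0502). BBM and SPT lost their calls with quantile normalization (adjusted p = 0.055 and 0.058), with centred arrays (0.12 and 0.13), and without any 1 array other than WOX5 replicate 2, where adjusted p reached 0.13.

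The third comparison took the genes that specify xylem, of which 4 were measured. PHV, a class III homeodomain-leucine zipper gene of vascular patterning, was lower in WOX5 cells, at 248 ± 33.6 against 517 ± 91.1 in TMO5 cells (SD, n = 3), a 2.08-fold difference (limma adjusted p = 0.019). IAA20, an Aux/IAA gene, was 2.15-fold higher in WOX5 cells, at 973 ± 196 against 450 ± 70.1. LHW, the partner of TMO5 in a heterodimer, had a log2 difference of 0.08 ± 0.23 (SE), and IAA30 one of -0.18 ± 0.26, and neither passed. The counts adjusted over the list alone were 1 higher and 1 lower as well, and camera gave an adjusted p of 0.86. PHV lost its call without WOX5 replicate 3 and without TMO5 replicates 1 or 2 (adjusted p up to 0.069), and IAA20 without WOX5 replicate 3 and without TMO5 replicates 2 or 3 (adjusted p up to 0.063). PHV and IAA20 also lost their calls with a replicate block (limma adjusted p = 0.051 and 0.070).

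**Figure D1:**
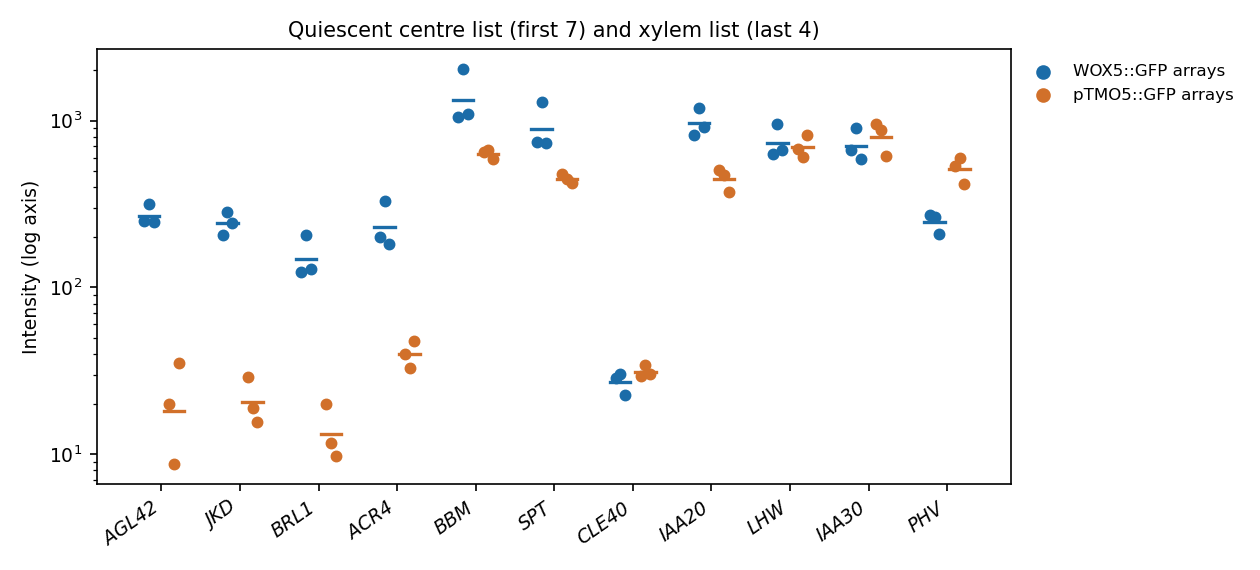
Intensity on each array (log axis) of the 7 measured quiescent centre genes and the 4 measured xylem genes; each point is 1 array and each bar the geometric mean of 3 arrays. AGL42, JKD, BRL1 and ACR4 lie higher on all WOX5::GFP arrays, while LHW and IAA30 overlap between the groups.

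Other lists fixed in advance held few measured genes. Of 8 auxin genes, 2 were higher and 4 lower in WOX5 cells, with the same counts adjusted over the list alone and a camera adjusted p of 0.19. The auxin list's median log2 difference of -0.97 stood at percentile 0.06 of random lists of matched brightness. GH3.5 (WES1 in the gene table), which like GH3.3 joins auxin to amino acids, was 9.92-fold lower, at 208 ± 75.4 against 1963 ± 206 (SD, n = 3; limma adjusted p = 0.0027). IAA29 was at least 7.49-fold lower and YUC2, an enzyme of auxin synthesis, 1.93-fold lower, whereas GH3.17 was 5.46-fold higher. GH3.3, GH3.17, YUC2 and IAA20 each lost the call when some single arrays were left out, including TMO5 replicates 2 and 3, with adjusted p up to 0.076, 0.062, 0.13 and 0.063. Rises in the list numbered 1 without WOX5 replicate 1 and 0 without WOX5 replicate 3 or TMO5 replicates 2 or 3, and falls 2 without any 1 TMO5 array. IAA30 and YUC6 did not pass.

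Of 4 ground tissue genes, JKD and CO2 (AT1G62500), a cortex marker, were higher in WOX5 cells, CO2 by 12.3-fold. GSO1 and PEP (AT1G09750) did not pass, with log2 differences of 0.08 ± 0.30 and -1.21 ± 0.35 (SE), and camera gave an adjusted p of 0.26. The ground tissue list's median log2 difference of 1.825 stood at percentile 98.87 of matched random lists. Adjusted over the list alone, 2 genes were higher and 1 lower. PEP passed as lower with quantile normalization (adjusted p = 0.023), centred arrays (0.021), a filter on dim probe sets (0.017) and an intensity trend with robust variances (0.015). Of 3 genes of wounding and protoplasting, WRKY6 was 2.97-fold higher in WOX5 cells and WRKY53 at least 1.22-fold lower, while ZAT10 (STZ) had a log2 difference of 0.96 ± 0.28 and did not pass. Adjusted over the list alone, 2 were higher and 1 lower, and the camera adjusted p was 0.48. WRKY53 lost its call with an intensity trend and robust variances (adjusted p = 0.057) and without any 1 array other than WOX5 replicate 2, with adjusted p up to 0.11. ZAT10 passed as higher with that trend (0.0076), with a filter on dim probe sets (0.019) and without TMO5 replicate 1 (0.038).

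The remaining fixed lists had 1 or 2 measured members and were not tested as lists. LBD16, a lateral root regulator, was 2.34-fold higher in WOX5 cells, and LBD29 of the same pericycle list, within background in both groups, did not pass. ACR4 is also on the root cap list, whose other member RCPG (AT1G65570) did not pass, and BRL1 is the 1 brassinosteroid gene measured. The Aurora kinases AUR1 and AUR2, which act in mitosis, were 2.64-fold and 2.03-fold lower in WOX5 cells. No member passed in the lists for cytokinin (ARR16, listed as RR16, 1.30 ± 0.69, and ARR15, -0.05 ± 0.99), phloem (OPS, -0.38 ± 0.33) or the secondary wall (IRX10, listed as GUT2, 0.67 ± 0.22), as log2 differences with SE. Both cytokinin genes lay within background in both groups, so their values say nothing about cytokinin. MCM7 (PRL, -0.11 ± 0.18), heat shock (HSP22.0, -1.75 ± 0.50) and photosynthesis (RCA, 0.05 ± 0.74) did not pass either. Nor did the ribosomal proteins PGY1 (-0.62 ± 0.19) and RPL4A (AT3G09630, -0.52 ± 0.16). All of these lay above background in both groups. Of the reference genes, SAND (AT2G28390) differed by -0.42 ± 0.16 and TIP41 (AT4G34270) by 0.10 ± 0.16, and neither passed. Adjusted over the list alone, IRX10 was higher and HSP22.0, PGY1 and RPL4A lower. SAND and HSP22.0 passed as lower with quantile normalization (adjusted p = 0.047 and 0.031), centred arrays (0.019 and 0.021), array weights (0.048 and 0.024) and an intensity trend with robust variances (0.041 and 0.0086). SAND also passed with a floor at the 20th percentile (0.036), and HSP22.0 with a filter on dim probe sets (0.017) and without WOX5 replicate 2 (0.046). PGY1 and RPL4A passed as lower with centred arrays (both 0.015), the filter (0.025 and 0.029), the floor (0.042 and 0.031) and the trend (0.013 and 0.017). IRX10 passed as higher with the filter (0.029) and the trend (0.044). ARR16 passed as higher with the floor (0.029), but this compares values within background in both groups. AUR2 lost its call without TMO5 replicates 2 or 3 (adjusted p up to 0.060).

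Among the lists added by locus, genes of mitosis were lower in WOX5 cells. Of 22 measured, 18 fell and 1, AT2G28620, rose. AT3G44050 was 4.47-fold lower, at 236 ± 28.9 in WOX5 against 1050 ± 48.5 in TMO5 cells (SD, n = 3; limma adjusted p = 0.0014). The spindle checkpoint gene BUBR1 was 3.55-fold lower, at 145 ± 28.4 against 511 ± 54.2. AT2G28620 stood at 238 ± 9.20 against 71.2 ± 13.2, a rise of 3.38-fold. The list's median log2 difference was -1.19, camera gave an adjusted p of 2.68e-08, and with an estimated correlation the adjusted p was 0.16. Adjusted over the list alone, 18 were lower and 2 higher. With an intensity trend and robust variances 2 were higher over all genes, and without TMO5 replicate 3 the count of falls over all genes was 11. Falls numbered 10 with a replicate block.

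Genes of DNA replication and core histones moved less. Of 6 replication genes, only the histone chaperone ASF1B passed, 1.70-fold lower in WOX5 cells, and the list's median log2 difference was -0.24 (camera adjusted p = 0.12), or -0.49 with quantile normalization and -0.62 with centred arrays. Of 8 histone genes, AT2G37470 and HTB1 were lower, by 2.28-fold and 1.72-fold, and AT3G53650 was 2.38-fold higher (camera adjusted p = 0.48). Adjusted over the list alone, the counts were the same in both lists. Replication genes lower in WOX5 cells numbered 5 with centred arrays, 3 with a floor at the 20th percentile and 2 with quantile normalization, a filter on dim probe sets or an intensity trend with robust variances. With a replicate block no gene of either list passed. ASF1B lost its call when any 1 array was left out (adjusted p up to 0.094), and HTB1 with quantile normalization (adjusted p = 0.055) and without WOX5 replicate 3 or any 1 TMO5 array (adjusted p up to 0.063).

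Genes for cytosolic ribosomal proteins were lower in WOX5 cells in 40 of 111 cases and higher in 0, and 75 were lower when adjusted over the list alone. AT5G59240 was 7.41-fold lower, at 252 ± 144 against 1577 ± 41.7 (SD, n = 3; limma adjusted p = 0.019), and AT3G04230 was 3.20-fold lower. The median log2 difference was -0.69 as deposited, -0.26 with quantile normalization and -1.06 with centred arrays. Camera gave an adjusted p of 2.12e-18, and with an estimated correlation the adjusted p was 0.31. The count of falls was 62 with a floor at the 20th percentile, 82 with a filter on dim probe sets and 88 with an intensity trend and robust variances. It was 18 with quantile normalization, 104 with centred arrays, 20 without WOX5 replicate 1 and 7, 6 and 11 without TMO5 replicates 1, 2 and 3. With a replicate block it was 5. AT5G59240 was 4.72-fold lower without WOX5 replicate 2 and lost its call without any 1 TMO5 array (adjusted p up to 0.063).

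Root hair genes were lower in WOX5 cells in 3 of 6 cases, namely AT5G04960, AT3G49960 and AT4G26010, and 3 falls were counted when adjusted over the list alone. AT5G04960 stood at 35.2 ± 2.42 in WOX5 against 130 ± 42.9 in TMO5 cells (SD, n = 3; limma adjusted p = 0.0097). The expansin genes EXPA7 and EXPA18 had log2 differences of -1.35 ± 0.51 and -0.67 ± 0.28 (SE) and did not pass. With centred arrays both passed as lower (adjusted p = 0.042 and 0.029), EXPA18 also with quantile normalization (0.039) and EXPA7 with a filter on dim probe sets (0.045) and an intensity trend with robust variances (0.036). Falls in the list numbered 5 with centred arrays and 5 with that trend. Camera gave an adjusted p of 0.0032, and with an estimated correlation the adjusted p was 0.29. Without WOX5 replicate 1 or TMO5 replicate 3, 1 gene of the list passed, and AT3G49960 lost its call without WOX5 replicate 1 or any 1 TMO5 array (adjusted p up to 0.11). Class III peroxidases went both ways, with 5 of 54 higher and 7 lower (camera adjusted p = 0.37). The peroxidase gene AT2G43480 was 38.7-fold higher in WOX5 cells and AT1G71695 12.7-fold lower. Adjusted over the list alone, 5 peroxidase genes were higher and 6 lower. Peroxidase falls numbered 11 with an intensity trend and robust variances, 3 without WOX5 replicate 1, 2 without WOX5 replicate 3 or TMO5 replicates 1 or 2, and 1 without TMO5 replicate 3. Rises numbered 3 without WOX5 replicates 1 or 3 or TMO5 replicate 3.

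**Figure D2:**
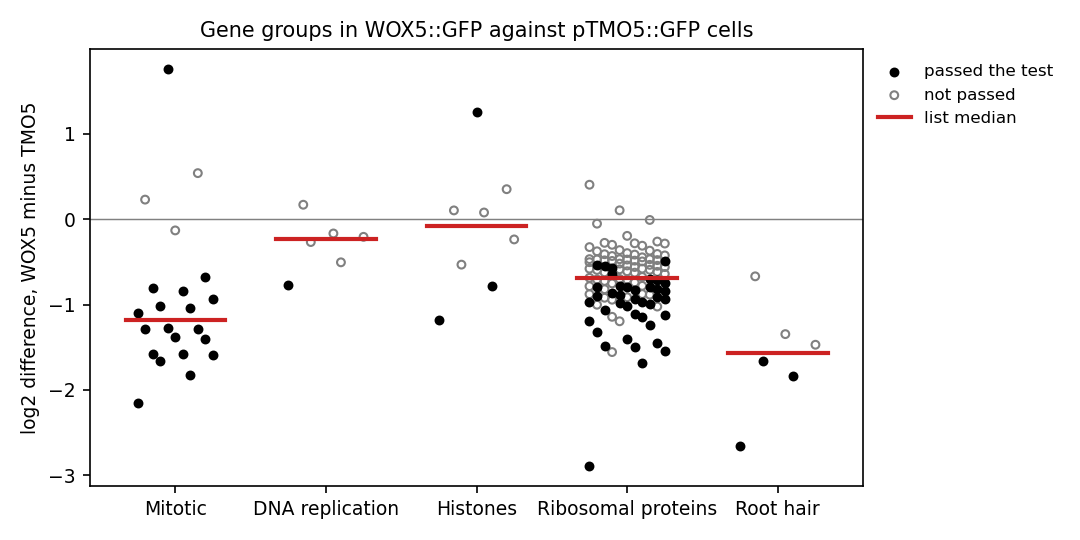
Log2 difference (WOX5 minus TMO5) of each gene in 5 lists; filled points passed the test over all probe sets, open points did not, and red lines are list medians. The mitotic median is -1.19 and the replication median -0.24, and the ribosomal median of -0.69 is -0.26 with quantile normalization.

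Spiked and internal controls gave the state of the arrays themselves. The bacterial hybridisation control bioB read 30.1 ± 3.75 on WOX5 and 380 ± 11.6 on TMO5 arrays, as the geometric mean of 6 probe sets on each array (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible). On the WOX5 arrays 2 of these probe sets lay within background. The brighter controls differed less, with bioC at 603 ± 50.02 against 1115 ± 21.8, bioD at 2166 ± 148 against 3144 ± 59.7 and cre at 10368 ± 666 against 15114 ± 574. RNA quality was read as the log2 ratio of 3′ to 5′ probe sets. For actin it was 1.72 ± 0.16 in WOX5 and 1.598 ± 0.13 in TMO5 arrays, for GAPDH 0.13 ± 0.06 and 0.32 ± 0.07, and for ubiquitin 0.70 ± 0.16 and 0.80 ± 0.09 (SD, n = 3; exact two-sided permutation p = 0.4, 0.1 and 0.4). In the older probe sets it was 0.98 ± 0.03 in WOX5 and 1.89 ± 0.04 in TMO5 arrays for GAPDH, 4.62 ± 0.39 and 4.14 ± 0.11 for actin, and 1.95 ± 0.17 and 1.78 ± 0.15 for ubiquitin (exact permutation p = 0.1, 0.2 and 0.3).

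**Figure D3:**
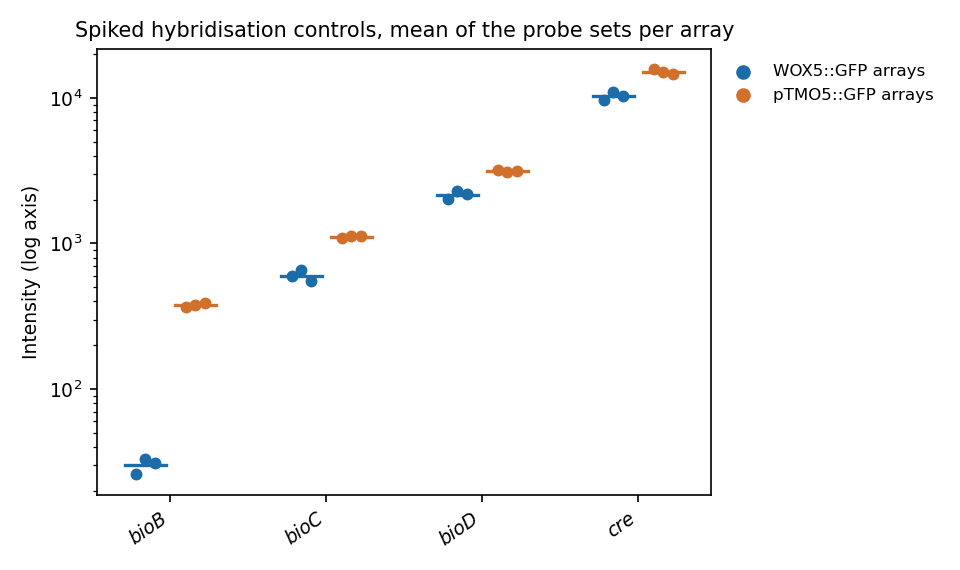
Intensity (log axis) of 4 spiked hybridisation controls; each point is 1 array, as the geometric mean of that control's probe sets, and each bar is the geometric mean of 3 arrays. The bioB points lie near 30.1 on WOX5::GFP arrays and near 380 on pTMO5::GFP arrays, a wider gap than for bioC, bioD or cre.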

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

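The test of a single dilution was chosen after the control values had been seen. The bioB control, which the comparisons of root genes do not use, was brighter on the TMO5 arrays than on the WOX5 arrays by at least 8.15-fold in each of its 6 probe sets, without overlap between the 3 arrays of each group. A loss of sensitivity for dim signals on the WOX5 arrays would lower other probe sets of the same brightness. Yet the 2263 probe sets as bright as bioB on the TMO5 arrays had a median log2 difference of -0.11. Its 95% bootstrap interval, drawn over probe sets and not arrays, was -0.14 to -0.08. A single dilution of the whole control mix would shift all controls alike, but the log2 difference of the bioB probe set that differed least, above background on all arrays, lay 2.49 below that of bioD (SE 0.15). A different mix or lot of controls may remain, and so may a different labelling or hybridisation of each group, neither of which was tested. No biological explanation applies to a spiked control.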

How the results depend on the processing

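The alternatives for the 6 lists added by locus were chosen after the annotation had been seen. Quantile normalization kept 4382 of the 5411 calls and centred arrays 4400, and no shared call turned its sign under any alternative. The brightness filter, intensity trend, replicate block and 2-fold minimum leave log2 differences unchanged, so no sign could turn there. Falls in WOX5 cells numbered 5297 with centred arrays, 3245 with a brightness filter, 3314 with an intensity trend and robust variances and 1103 with a 2-fold minimum, against 2159; other totals under these settings stayed within 1.5 times of the main counts. With 1 array left out, calls numbered 2827 to 4854, rises 2101 to 2854 and falls 726 to 2000, with fewer arrays in each fit. With an estimated correlation, camera's adjusted p was 0.3535 for the quiescent centre list, 0.1641 for mitotic, 0.3067 for ribosomal and 0.2904 for root hair genes. Replication genes passed with centred arrays (camera adjusted p = 0.03985) and with a floor at the 20th percentile (0.02955). The cause was not tested. Fry does not set a list against other genes, and its p-values were not adjusted. It gave p of 0.0010 for the quiescent centre, 0.0022 for auxin, 0.0038 for ground tissue, 0.00051 for wounding and 0.92 for xylem. For mitotic, ribosomal and root hair genes fry gave 8.6e-05, 0.0085 and 0.0065. For replication, histone and peroxidase genes it gave 0.00061, 0.098 and 0.80.

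The xylem list turned upward with quantile normalization (camera adjusted p = 0.8384), although its mean stayed negative at -0.03. With 1 array left out its p ran from 0.6131 to 0.9999, and it turned upward without WOX5 replicates 1 or 3 (means 0.04 and 0.08); its mean was also positive without TMO5 replicates 1 or 2 (0.05 and 0.02), where camera's direction stayed downward. Core histones turned upward in camera's ranking with quantile normalization (0.8454), although their mean stayed negative at -0.08. Among named genes that had not passed, log2 differences changed sign with quantile normalization for RCA (-0.12), MCM7 (PRL, 0.019), GSO1 (-0.14) and TIP41 (-0.041). With centred arrays they did so for RCA (-0.32), GSO1 (-0.30), TIP41 (-0.28) and LHW (-0.29), and with array weights for LHW (-0.011). With 1 array left out they ran from -0.46 to 0.91 for RCA, -0.19 to 0.023 for MCM7, -0.96 to 0.66 for ARR15, -0.15 to 0.36 for GSO1 and -0.10 to 0.20 for LHW; the cause was not tested. None of the 52 named genes that passed changed sign under the settings tried, several of which leave log2 differences unchanged. The brightness filter left only 48 of the 52, and up to 13 lost the call under a single setting. Of the 22 that had not passed, 10 passed under some setting, among them 4 with quantile normalization and 7 with centred arrays.

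Same-numbered arrays did not deviate together (r = -0.12, 0.01 and 0.02), so no pairing by number was seen. These values cannot exclude one, because the deviations within a group depend on each other. With a replicate block, calls numbered 2270, with 1719 rises and 551 falls. Falls then numbered 5 among ribosomal protein, 10 among mitotic and 1 among root hair genes. No xylem or histone gene passed. The quiescent centre list had 4 rises, and the auxin list 0 rises and 3 falls. The block took the call from 13 of the 52 named genes that had passed. They were BBM, SPT, GH3.17, IAA20, PHV, AUR2, WRKY53, YUC2, AT3G49960, AT3G53650, AT2G37470, HTB1 and ASF1B, with limma adjusted p from 0.051 to 0.12. The reporter check and the transcription factor test were not run. Signal over background limits the folds of 937 called probe sets whose dimmer group lay within background, and in 256 of the calls both groups did.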

Other observations

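The families named here, and the test of mitotic against replication and histone genes, were chosen after fold changes had been seen. Of 47 genes for UDP-glycosyltransferases (UGT), which attach sugars to small molecules, 13 were higher in WOX5 cells and 1, UGT73D1, was lower. UGT73B4 stood at 1207 in WOX5 against 99.4 in TMO5 cells (limma adjusted p = 0.0016), and UGT72E2, UGT71B1 and UGT85A2 were higher by 3.22, 3.15 and 2.49 on the log2 scale. Of 11 genes for tau-class glutathione transferases (GSTU), 6 were higher, GSTU25 by 2.70 and GSTU27 by 2.07 on the log2 scale, and 1, GSTU28, was lower. Of 8 aldehyde dehydrogenase (ALDH) genes, 5 were higher, among them ALDH6B2 (1543 against 386) and ALDH7B4 (2700 against 896), and ALDH10A9 was lower.

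Camera adjusted over 31 families gave 0.022 for UGT, 0.023 for GSTU and 0.022 for ALDH, and with an estimated correlation the adjusted p was 0.58 for each. Family medians stayed positive with quantile normalization (0.40, 0.94 and 1.31) and with centred arrays (0.19, 0.83 and 0.86). The GSTU call was lost without WOX5 replicate 2 (adjusted p = 0.058) and without TMO5 replicate 3 (adjusted p = 0.052). With a filter on dim probe sets, adjusted p was 0.16 for GSTU, of which 6 genes were left, and 0.080 for ALDH, so both calls were lost. The UGT count of rises was 8 without any 1 of the TMO5 arrays, and UGT falls numbered 3 with quantile normalization, 4 with centred arrays and 0 without TMO5 replicates 2 or 3. ALDH falls numbered 0 without any 1 array other than WOX5 replicate 2. Of 8 genes sharing the symbol stem rps, in upper or lower case, 4 were lower in WOX5 cells, rps2 by the most at 418 against 1089. The stem alone does not give the kind of protein each gene encodes. The family had a camera adjusted p of 0.022 and an adjusted p of 0.58 with an estimated correlation. The rps call was lost with a filter on dim probe sets (adjusted p = 0.080). The count of rps falls was 2 without TMO5 replicate 1 and 2 without TMO5 replicate 2, and 7 with centred arrays, the filter, or an intensity trend with robust variances.

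The fall of mitotic genes in WOX5 cells was weighed against scaling, a single array and a general loss of cycling cells. Quantile normalization left the list median at -1.22, at percentile 0 of 10000 random lists of matched brightness, and leaving out WOX5 replicate 2 left it at -1.18 with 17 falls, which argues against scaling, a brightness trend or that array alone as the cause. A lower share of dividing cells in every cycle phase was taken to lower replication and histone genes as far. These 14 genes had a median of -0.22 and differed from the mitotic genes (permutation p = 0.0070, across genes, which are not independent). The medians were -0.40 against -1.22 with quantile normalization (permutation p = 0.0046) and -0.60 against -1.56 with centred arrays (0.0062). That replication and histone genes would fall as far was assumed and not tested, so the comparison cannot set aside a general loss of cycling cells. Such a loss may remain, as may a difference limited to the mitotic phase. So may a difference in sorting or array handling, which cannot be told apart from cell type here.

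The fall of ribosomal protein genes was weighed against scaling and a single array. With quantile normalization the list median of -0.26 stood at percentile 25.1 of matched lists, so array scaling or a brightness trend is a candidate explanation. The percentile was 0.03 on the values as deposited, however. Camera, which does not match brightness, still gave the list as lower with quantile normalization at the preset correlation of 0.01 (adjusted p = 0.00046). The estimated correlation of the list was 0.66. With it, camera's adjusted p was 0.31 on the values as deposited. The brightest 20% of all probe sets, which hold 108 of these 111 genes, had a median log2 difference of -0.28. Leaving out WOX5 replicate 2 left the list median at -0.51, which argues against that array alone. The upper 95% bootstrap limit was -0.45, but it was drawn over genes, which are not independent. It does not measure the spread between arrays. A biological difference between the cell types stays open and was not tested.

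With 3 arrays per group there are 10 splits of the 6 arrays, too few for a share under 0.05. In each of 4 results, 1 split, the real one, gave a value as large. Every other split puts arrays of both groups on each side. A group difference then widens the spread within each side and shrinks the mean shift. Lower values in the other splits follow from this mixing and are not separate support. The real split called 5411 probe sets with limma and the highest other split 0, with at most 662 at an unadjusted p under 0.05 in any other split. The mean log2 shift was 2.19 against at most 0.995 in other splits for the quiescent centre list, 0.96 against 0.41 for the mitotic list and 0.73 against 0.38 for the ribosomal protein list, as absolute values.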
